A study of Mus musculus with 12 samples.

How the data were processed

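Hearts of 12 C57BL/6 mice in 4 groups of 3 were sequenced. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase I and made into libraries with a SMARTER mRNA kit. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. Nothing in the labels says that a replicate number marks a shared litter, batch or day.

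The deposited table holds 24775 genes by 12 libraries. Its values are a signal: gene counts divided by 1 size factor per library, as the deposited values show, since each value is a whole multiple of the smallest step of its column. Per the file headers, the table also carries a column named baseMean, which equals the mean of the 12 libraries. Dividing by the step recovered whole reads for 100% of values within a tolerance of 0.01. In PRODH TAC replicate 1 the step lies at 0.993, near that of whole numbers, but its deposited values are not whole. Totals of recovered reads ran from 10.1 to 15.2 M. Of the gene identifiers 24735 matched the GENCODE M21 annotation, 24104 with the same symbol. No mitochondrially encoded gene is listed. Replicates within a group differed by more than sampling noise, with chi-square per degree of freedom from 4.63 to 95.44, so each library counts as 1 replicate.

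The design fixed before the data were examined had edgeR on raw counts as the main test and limma for a table without raw counts. The latter branch was used. The main test was limma 3.58.1 with a trended prior in R 4.3.3, on log2(value + 1), for genes with a value of at least 1 in at least 3 libraries (21173 genes). All 12 libraries were fitted together with a mean per group and a shared spread, at a Benjamini-Hochberg adjusted p under 0.05. The 5 comparisons were TAC against sham in vector mice, PRODH against vector in TAC mice, PRODH against vector in sham mice, TAC against sham in PRODH mice, and the difference between both TAC responses. A test of 3 animals against 3 by permutation cannot go below p = 0.1, so the p-values rest on the model.

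Gene lists fixed beforehand, 40 in number, were tested with limma camera at a preset correlation of 0.01 for those with at least 5 measured members. Camera with an estimated correlation and fry were alternatives. Camera called 18, 17, 14, 14 and 15 lists in the 5 comparisons in the order above. With an estimated correlation 0 were called in each, and fry called 12, 12, 0, 1 and 0. Fry asks whether the genes of a list move one way and does not compare them with other genes.

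Genes named in the text followed a rule fixed beforehand. Prodh was named in each comparison and a further 11 genes in both comparisons of the series' aims. Added were the 6 largest called rises and falls there (3 in the others) with a mean of at least 1 and no overlap between the groups, and up to 4 members with the smallest p per list described. Of these list members fewer were named in places, mostly those whose call held without any single library, a selection made after the values were seen. Chance gives no overlap in 10% of genes with 3 libraries against 3. A gene that the rule names among the falls after TAC in vector mice is not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

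Folds against a group with 0 reads were computed against a floor of 3 reads over the group, and those against 1 to 3 reads carry an exact binomial 95% interval. Intervals and floors cover counting error only. For the overlap of opposite changes, 100 simulations of unchanged groups shared the vector TAC libraries.

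The procedure was tested on simulated data with known changes. For TAC against sham in vector mice, on 21681 genes, it recovered 11.3% of 1.5-fold, 61.4% of 2-fold and 94.1% of 4-fold changes, with 3 false calls of 117. For PRODH against vector in TAC mice, on 21707 genes, it recovered 8.8%, 56.5% and 91.9%, with 8 false calls of 120. Few genes were changed, and none of them had few reads. The simulated noise was independent between genes, with no length trend and no outlying library. These rates may therefore not hold for genes with few reads or for the real libraries.

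Alternatives fixed beforehand were another pseudocount (0.1), other filters, quantile, upper quartile and library size scaling, only the 2 groups compared, the replicate number as a block, edgeR 4.0.16, DESeq2 1.42.0 and limma voom on the recovered reads, a minimum fold of 1.5, and leaving out each library in turn. Chosen after seeing the data were edgeR with TMM on the recovered reads, TMM scaling, thinning to the lowest total, the fit without vector TAC replicate 1 and PRODH sham replicate 2, mesothelial marker level as a covariate, and removal of a trend on transcript length and GC content. That trend was a natural spline with 5 degrees of freedom per property, fitted per library. It was fitted first on all genes with a length and then again on genes with a mean above 100 alone. The second version was added after the values of the first were seen, and results of both are given. The first left part of the length correlation for PRODH in sham mice (Spearman's rho = -0.202), TAC in PRODH mice (0.226) and the difference between TAC responses (0.141). The second left -0.001, 0.017 and 0.01 there. Figures were drawn with matplotlib 3.10.9.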

Results

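The hearts of 12 C57BL/6 mice were profiled by RNA sequencing. Each mouse had received an adeno-associated virus of serotype 9, a vector that reaches heart muscle, carrying either no gene of interest (vector) or the gene for PRODH. PRODH is proline dehydrogenase, the mitochondrial enzyme that starts the breakdown of proline. Surgery followed 3 weeks after the injection and was either transverse aortic constriction (TAC), which narrows the aorta and loads the heart with pressure, or a sham operation. Tissue was taken 4 weeks after surgery. The 4 groups of 3 libraries were vector sham, PRODH sham, vector TAC and PRODH TAC. The libraries held 10.1 to 15.2 M recovered reads each, with group means of 11.31 M in vector sham, 10.7 M in PRODH sham, 13.25 M in vector TAC and 10.5 M in PRODH TAC. Changes are log2 differences ± standard error from limma on log2(value + 1), with n = 3 per group and Benjamini-Hochberg adjusted p. This scale understates the change of genes with few reads.

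Prodh (ENSMUSG00000003526), the gene that the virus was meant to supply, was highest in the PRODH groups. Its normalized read count was 335.0 ± 43.9 (SD, n = 3) in vector sham, 844.6 ± 306.0 in PRODH sham, 192.2 ± 46.5 in vector TAC and 1101.6 ± 191.2 in PRODH TAC. In TAC hearts it rose by 2.52 ± 0.24 with the PRODH virus (limma adjusted p = 0.00017). In sham hearts the difference was 1.26 ± 0.24 and did not pass over all genes (limma adjusted p = 0.62), although the lowest PRODH sham library, at 496.7, lay above the highest vector sham library, at 379.3. Without PRODH sham replicate 2, the lowest of its group, the difference was 1.61 and passed the test (limma adjusted p = 0.028), and with DESeq2 on the recovered reads it was 1.33 and passed. After TAC the gene differed by -0.82 ± 0.24 in vector mice (limma adjusted p = 0.055) and by 0.45 ± 0.24 in PRODH mice (limma adjusted p = 0.63), neither past the threshold. The value in vector mice passed at -1 without vector TAC replicate 1 and at -0.82 without PRODH sham replicate 2. The table holds 1 entry for Prodh, and whether reads from the viral copy are counted in it is not given in the sources used here.

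**Figure D1:**
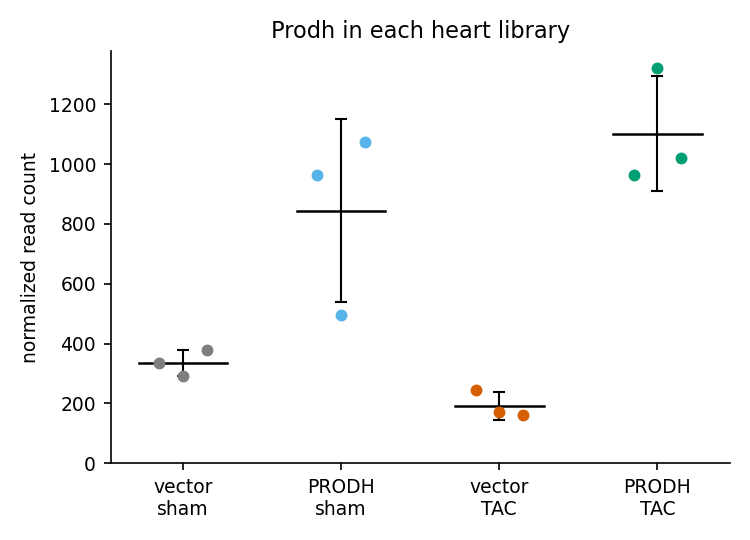
Normalized read count of Prodh (vertical axis, linear, from 0) in each of the 12 heart libraries (points), by group, with the group mean (line) and SD (bar). The 3 PRODH sham libraries lie between 496.7 and 1072.1 and the 3 PRODH TAC libraries between 963.9 and 1319.9, above all vector libraries, whose highest value is 379.3.

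The first aim of the series was to compare TAC with sham surgery in vector mice. Genes of the stressed and fetal heart rose after TAC. Nppa and Nppb, which encode the natriuretic peptides released by stretched heart muscle, rose by 4.37 ± 0.41 and 2.78 ± 0.18 (limma adjusted p = 3.2e-05 and 2.8e-06). Myh7, the slow myosin heavy chain, rose by 3.54 ± 0.47, and Acta1, skeletal muscle actin, by 4.34 ± 0.64. Nppa went from 623.5 ± 182.1 normalized reads in vector sham to 14475.1 ± 8358.8 in vector TAC. Matrix genes rose as well, among them Postn (periostin, secreted by activated fibroblasts) by 4.11 ± 0.4, Col1a1 by 2.06 ± 0.42 and Col3a1 by 1.83 ± 0.29. Atp2a2, the calcium pump of the sarcoplasmic reticulum, differed by -0.92 ± 0.38 and did not pass (limma adjusted p = 0.19), except without vector TAC replicate 1, where it did at -0.96. Cpt1b, which brings fatty acids into mitochondria, differed by -0.38 ± 0.28 (limma adjusted p = 0.52).

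In the proline pathway of the same comparison, Aldh4a1, the enzyme that follows PRODH in proline breakdown, fell by 0.79 ± 0.15 on the log2 scale. Pycr1 and Aldh18a1, which make proline, rose by 1.73 ± 0.37 and 0.97 ± 0.18. Of the 21 measured members of the proline and glutamate list, 2 rose and 5 fell, and 2 rose and 9 fell adjusted over the list alone. As a set the list did not pass limma camera (adjusted p = 0.052). Gpt2, an alanine aminotransferase, fell by 1.5 ± 0.19, and Slc25a12, a mitochondrial carrier of aspartate and glutamate, fell by 0.68 ± 0.13.

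Among the largest rises after TAC, Fmod (fibromodulin, a collagen-binding proteoglycan) rose by 6.54 ± 0.83, Thbs4 (thrombospondin 4) by 6.0 ± 0.67 and Cthrc1, a secreted protein of activated fibroblasts, by 5.7 ± 0.64. Atp6v0a4, a proton pump subunit, rose by 5.67 ± 0.78 and Serpinb1c, a serpin, by 5.55 ± 0.7. Tnmd (tenomodulin, a tendon protein) had 0 reads in vector sham and 346 in vector TAC, at least 94.4-fold higher against a floor of 3 reads over the group. Among the largest falls were Aqp4, a water channel (-5.15 ± 0.6), Retnla, a secreted protein of alternatively activated macrophages (-4.27 ± 0.5), and Cacng6, a calcium channel subunit (-4.18 ± 0.51). Cyp1a1, a cytochrome P450, fell by 3.76 ± 0.9, a call that was lost without vector sham replicate 1 (-3.59) or 2 (-3.75) or vector TAC replicate 2 (-2.61) or 3 (-3.39). Rp1 had 64 reads in vector sham and 3 in vector TAC, a ratio of 26.1 (95% counting interval 8.53 to 129.8). Its call was lost without vector sham replicate 1 (-2.91) or 2 (-3.4) or vector TAC replicate 2 (-3.54).

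Gene groups fixed before the data were examined moved as sets after TAC in vector mice. Of 77 extracellular matrix genes, 55 rose and 1 fell (65 and 1 adjusted over the list alone), with a median of 1.46 (limma camera adjusted p = 3.5e-43). With an estimated correlation between genes this became adjusted p = 0.13 with an estimated correlation. Cilp, a cartilage matrix protein, rose by 4.77 ± 0.36, and the microfibril proteins Mfap4 and Mfap5 rose by 2.94 ± 0.23 and 2.52 ± 0.24. Of 30 genes of TGF-beta signalling and myofibroblasts, 19 rose and 1 fell (23 and 2 adjusted over the list alone), among them Itgbl1 (2.64 ± 0.28), Frzb, a secreted Wnt antagonist (2.69 ± 0.3), and Ltbp2, which binds microfibrils (5.09 ± 0.6). The set had a limma camera adjusted p = 4.6e-17, and adjusted p = 0.13 with an estimated correlation. Of 27 hypertrophy and fetal genes, 15 rose and 3 fell, the same counts adjusted over the list alone, with limma camera adjusted p = 3.4e-11 and adjusted p = 0.13 with an estimated correlation. Ankrd1, a stretch-responsive cofactor of heart muscle, rose by 2.69 ± 0.24, and Ccn2, connective tissue growth factor, by 2.9 ± 0.28.

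Metabolic and ion-handling groups went the other way. Of 48 fatty acid oxidation genes, 32 fell and 0 rose (38 fell adjusted over the list alone), with limma camera adjusted p = 3.5e-23 and adjusted p = 0.13 with an estimated correlation. Fitm2, which acts in lipid storage (-1.11 ± 0.15), and Acss1, mitochondrial acetyl-CoA synthetase (-1.03 ± 0.16), fell. Of 23 genes of branched-chain amino acid breakdown, 16 fell (17 adjusted over the list alone), including Ppm1k, the phosphatase that activates the pathway (-1.5 ± 0.19), with limma camera adjusted p = 1.4e-16 and adjusted p = 0.14 with an estimated correlation. Of 22 tricarboxylic acid cycle genes 11 fell (19 adjusted over the list alone), with limma camera adjusted p = 1.8e-13 and adjusted p = 0.18 with an estimated correlation. Idh3a, an isocitrate dehydrogenase subunit, fell by 0.77 ± 0.15. Of 43 genes of calcium handling and ion channels 21 fell (28 adjusted over the list alone), with limma camera adjusted p = 2.3e-20 and adjusted p = 0.13 with an estimated correlation. Kcnj3, a potassium channel, fell by 2.08 ± 0.19. Of 76 oxidative phosphorylation genes 3 fell and 73 did not pass (3 also adjusted over the list alone), with a median of -0.44 (-0.71 without vector TAC replicate 1), limma camera adjusted p = 7.7e-14 and adjusted p = 0.51 with an estimated correlation.

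Cell type markers and other lists also differed in vector TAC hearts. Of 15 cardiac fibroblast markers 5 rose and 1 fell (7 and 1 adjusted over the list alone), with limma camera adjusted p = 0.00017 and adjusted p = 0.13 with an estimated correlation. Pi16 rose by 1.53 ± 0.24 and Scara5 fell by 1.78 ± 0.2. Of 8 chondrocyte and valve markers 5 rose (6 adjusted over the list alone), with limma camera adjusted p = 1.1e-06 and adjusted p = 0.14 with an estimated correlation. Comp, a cartilage matrix protein, rose by 5.49 ± 0.84 and Sox9, a transcription factor of cartilage, by 2.46 ± 0.43. Of 20 macrophage markers 3 rose (6 adjusted over the list alone), with limma camera adjusted p = 0.00013 and adjusted p = 0.46 with an estimated correlation. This call was lost without vector TAC replicate 1, where the median was 0.27. Of 34 interferon response genes 3 rose (8 adjusted over the list alone), with a median of 0.55, limma camera adjusted p = 1.5e-08 and adjusted p = 0.34 with an estimated correlation. Of 23 immediate early genes, a list that also reacts to tissue handling, 7 rose (10 adjusted over the list alone), with a median of 0.34, limma camera adjusted p = 3.3e-05 and adjusted p = 0.46 with an estimated correlation. That median was 0.55 and 0.08 without vector sham replicates 1 and 3, and 0.61 and 0.1 without vector TAC replicates 1 and 3. Of 12 ventricular myocyte markers 1 fell (1 adjusted over the list alone), with a median of -0.42, limma camera adjusted p = 0.0089 and adjusted p = 0.2 with an estimated correlation. None of 15 endothelial markers passed, also adjusted over the list alone. Markers of the epicardium and mesothelium, the cell layers that cover the heart, stood 3.33 above the vector sham mean in vector TAC replicate 1, against 0.83 and 0.48 in replicates 2 and 3. In the same library the matrix list stood at 0.95, against 2.45 and 2.15.

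**Figure D2:**
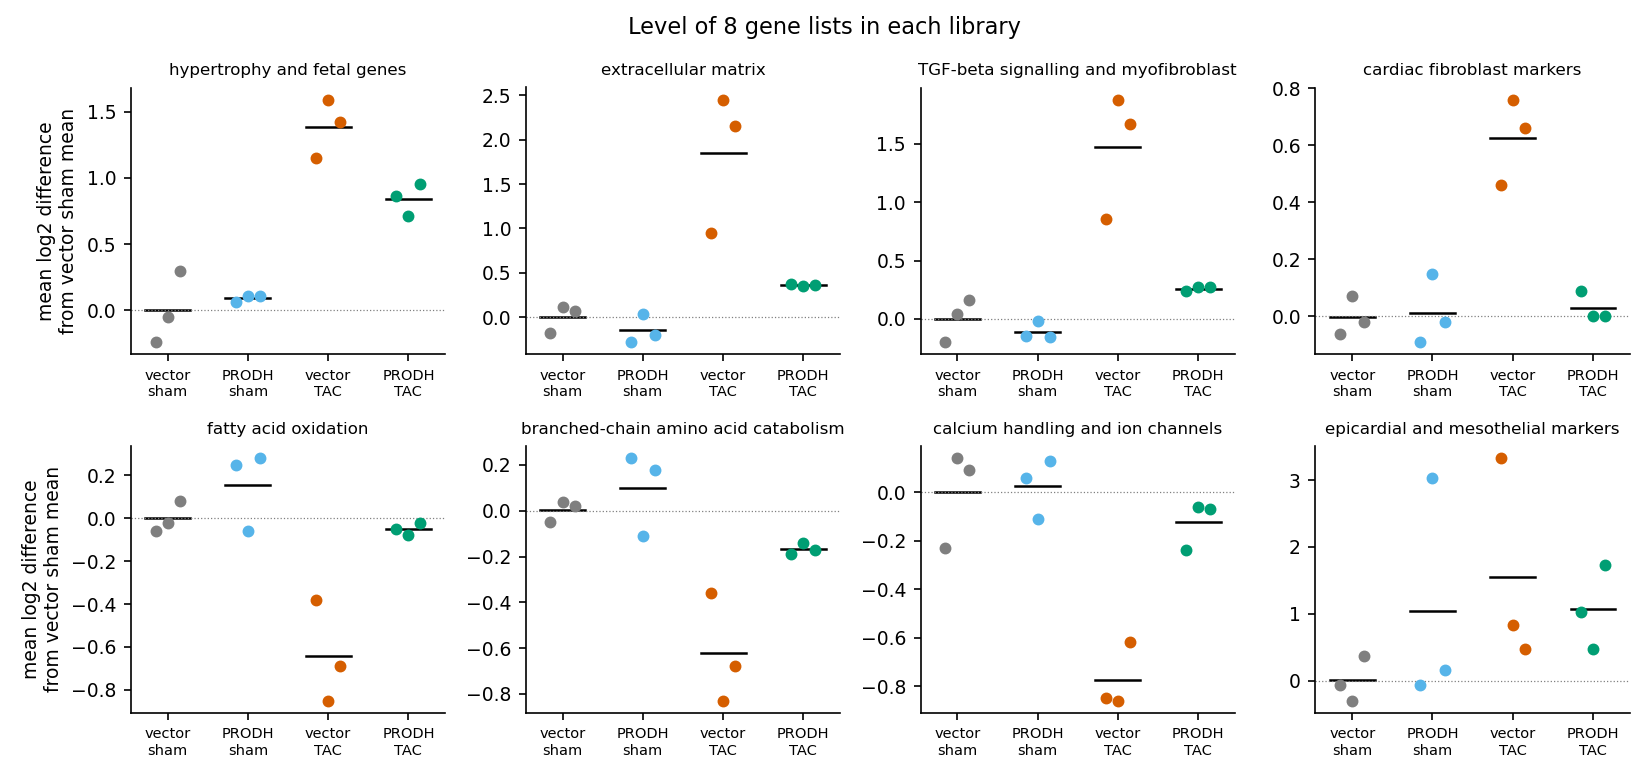
Mean log2 difference from the vector sham mean (vertical axes, linear) of 8 gene lists in each of the 12 libraries (points), with group means (lines). The extracellular matrix list reads 0.95, 2.45 and 2.15 in vector TAC and 0.37, 0.35 and 0.36 in PRODH TAC.

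In all, 787 genes rose and 858 fell among 21173 tested after TAC in vector mice, 1379 of them by at least 1.5-fold and 778 by at least 2-fold. The total of 1645 became 957 without vector sham replicate 2, 1088 without vector sham replicate 3, 3420 without vector TAC replicate 1, 817 without vector TAC replicate 2 and 1063 without vector TAC replicate 3. A fit of only these 2 groups gave 652, and 3513 were called without vector TAC replicate 1 and PRODH sham replicate 2, the libraries richest in mesothelial markers, a setting chosen after seeing the data.

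The second aim was to compare the PRODH virus with the vector after TAC. Natriuretic peptide and matrix genes were lower in PRODH TAC hearts. Nppa fell by 3.28 ± 0.41 (limma adjusted p = 0.00095), from 14475.1 ± 8358.8 normalized reads in vector TAC to 1358.5 ± 477.6 in PRODH TAC. Nppb fell by 1.05 ± 0.18. Myh7 fell by 2.53 ± 0.47, a call lost without PRODH TAC replicate 2 (-2.29). Postn fell by 3.25 ± 0.4. Col3a1 fell by 1.45 ± 0.29, a call lost without vector TAC replicate 2 (-1.13) or PRODH TAC replicate 2 (-1.4) or 3 (-1.47). Col1a1 differed by -1.55 ± 0.42 and narrowly missed the threshold (limma adjusted p = 0.052), passing without vector sham replicate 1 (-1.55) or vector TAC replicate 1 (-2.24). Acta1 (-1.17 ± 0.64), Atp2a2 (0.74 ± 0.38) and Cpt1b (0.63 ± 0.28) did not pass, with limma adjusted p = 0.39, 0.36 and 0.28.

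**Figure D3:**
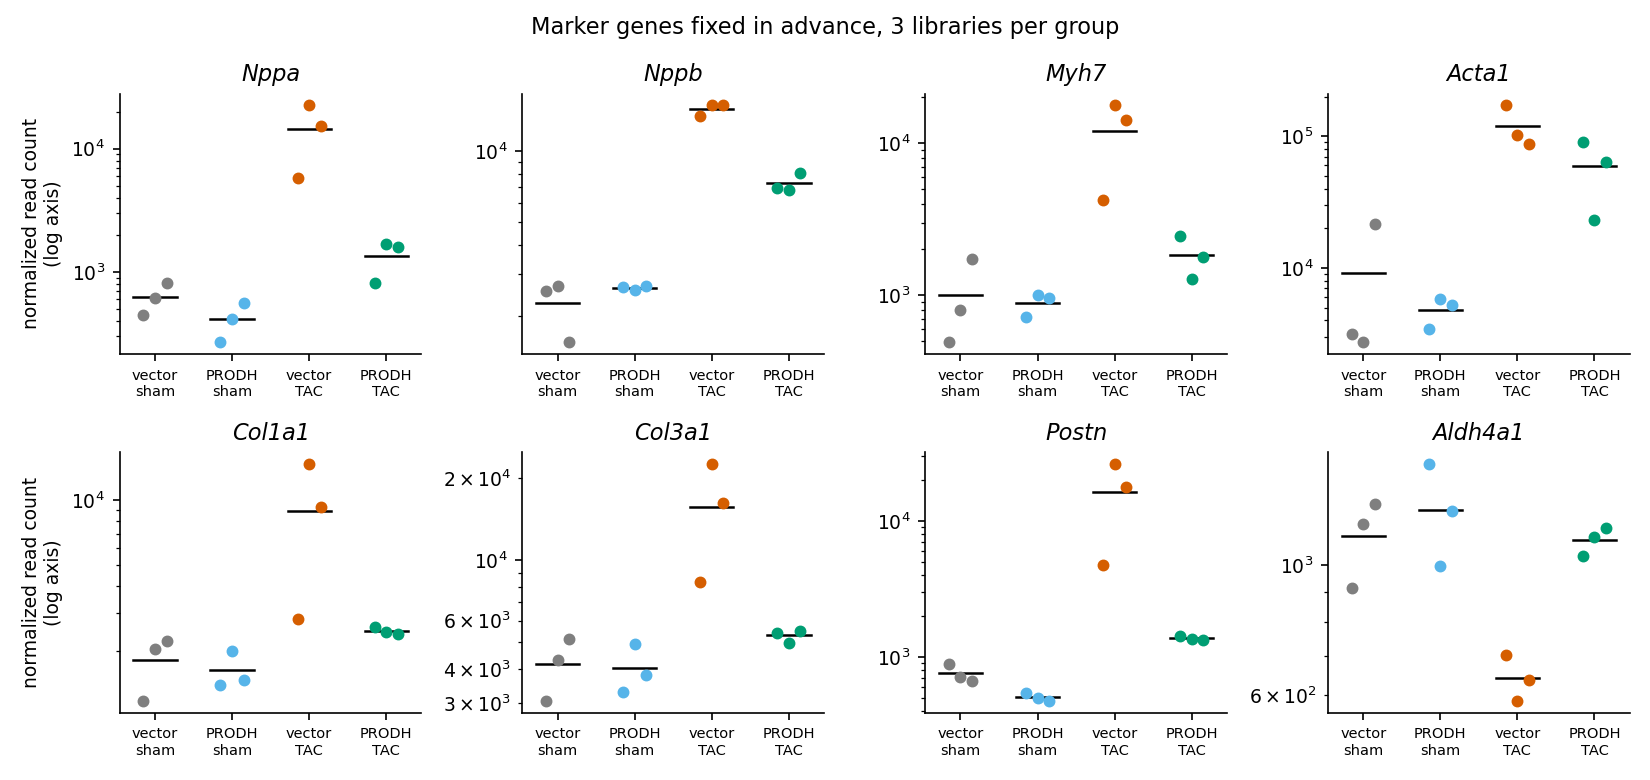
Normalized read counts (vertical axes, log scale) of 8 marker genes fixed before the data were examined, in each of the 12 libraries (points), with group means (lines). Nppa averages 14475.1 in vector TAC and 1358.5 in PRODH TAC, against 623.5 in vector sham.

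Within the proline pathway, Prodh itself rose by 2.52 ± 0.24 with the PRODH virus after TAC, and Slc25a22, a mitochondrial glutamate carrier, by 0.93 ± 0.17. Aldh4a1 rose by 0.79 ± 0.15, which did not pass without vector TAC replicate 2 (0.72) or PRODH TAC replicate 2 (0.77) or 3 (0.75). Its normalized read count was 640.8 ± 58.2 in vector TAC and 1103.0 ± 60.6 in PRODH TAC. Pycr1 differed by -1.25 ± 0.37 (limma adjusted p = 0.075). Of the 21 members of the proline and glutamate list 5 rose and 1 fell (8 and 4 adjusted over the list alone), and the set did not pass limma camera (adjusted p = 0.066).

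The largest falls in PRODH TAC against vector TAC included Fmod (-5.94 ± 0.83), Thbs4 (-5.18 ± 0.67), Cthrc1 (-4.69 ± 0.64) and Ecrg4, a secreted peptide precursor (-5.36 ± 0.77). Chodl (chondrolectin) had 151 reads in vector TAC and 0 in PRODH TAC, at least 38.5-fold lower. Tnmd had 346 reads in vector TAC and 2 in PRODH TAC, a ratio of 132.2 (95% counting interval 36.3 to 1096.3). Besides Prodh, the largest rises were Retnla (3.92 ± 0.5), Aqp4 (3.4 ± 0.6), the dopamine receptor gene Drd2 (3.36 ± 0.74), Rasef (2.48 ± 0.55) and Sbk3, a kinase gene (2.47 ± 0.44). Drd2 was no longer called without vector TAC replicate 2 (3.18) or 3 (2.78) or PRODH TAC replicate 2 (2.94) or 3 (3.3). Rasef was no longer called without vector TAC replicate 2 (2.36) or PRODH TAC replicate 2 (2.23) or 3 (2.46).

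As sets, matrix genes were lower and metabolic genes higher in PRODH TAC. Of 77 extracellular matrix genes 41 fell and 0 rose (60 fell and 1 rose adjusted over the list alone), with a median of -1.16, limma camera adjusted p = 4.2e-43 and adjusted p = 0.16 with an estimated correlation. Cilp (-3.56 ± 0.36), Mfap4 (-2.14 ± 0.23) and Mfap5 (-2.14 ± 0.24) fell. Of 30 TGF-beta and myofibroblast genes 15 fell and 1 rose (24 and 1 adjusted over the list alone), with limma camera adjusted p = 4.8e-18 and adjusted p = 0.16 with an estimated correlation. Ltbp2 (-3.84 ± 0.6) and Frzb (-2.24 ± 0.3) fell. Of 27 hypertrophy and fetal genes 9 fell and 1 rose (12 and 6 adjusted over the list alone), with limma camera adjusted p = 0.0049 and adjusted p = 0.34 with an estimated correlation. Nmrk2, a muscle kinase of NAD synthesis, fell by 1.53 ± 0.26. Of 15 fibroblast markers 5 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -0.35, limma camera adjusted p = 1.2e-06 and adjusted p = 0.16 with an estimated correlation. The median was -0.54 without vector TAC replicate 3 and -0.54 and -0.69 without PRODH TAC replicates 1 and 3. Dcn (decorin) fell by 1.05 ± 0.17. Of 8 chondrocyte and valve markers 5 fell (6 adjusted over the list alone), with limma camera adjusted p = 4.4e-06 and adjusted p = 0.2 with an estimated correlation. Of 20 macrophage markers 2 fell (2 adjusted over the list alone), with a median of -0.54 (-0.32 without vector TAC replicate 1), limma camera adjusted p = 3.6e-06 and adjusted p = 0.4 with an estimated correlation.

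Of 48 fatty acid oxidation genes 19 rose and 0 fell (38 rose adjusted over the list alone), with limma camera adjusted p = 3.2e-23 and adjusted p = 0.16 with an estimated correlation. Ppargc1b, a coactivator of mitochondrial genes, rose by 1.6 ± 0.25, and Esrrg, a nuclear receptor of heart metabolism, by 0.8 ± 0.13. Of 43 genes of calcium handling and ion channels 16 rose (23 adjusted over the list alone), with limma camera adjusted p = 1.7e-18 and adjusted p = 0.16 with an estimated correlation. Kcnj3 rose by 1.58 ± 0.19 and Hcn2, a pacemaker channel, by 1.13 ± 0.16. Of 23 genes of branched-chain amino acid breakdown 8 rose (16 adjusted over the list alone), with limma camera adjusted p = 2.4e-13 and adjusted p = 0.24 with an estimated correlation. Ppm1k rose by 1.16 ± 0.19 and Aldh6a1 by 0.81 ± 0.14. Of 22 tricarboxylic acid cycle genes 2 rose (14 adjusted over the list alone), with limma camera adjusted p = 8.5e-11 and adjusted p = 0.27 with an estimated correlation. Of 12 ventricular myocyte markers 2 rose (3 adjusted over the list alone), with limma camera adjusted p = 0.001 and adjusted p = 0.16 with an estimated correlation. Of 76 oxidative phosphorylation genes 1 rose (0 adjusted over the list alone), with a median of 0.27, limma camera adjusted p = 1.2e-07 and adjusted p = 0.66 with an estimated correlation. The median was 0.55, 0.09 and 0.11 without vector TAC replicates 1, 2 and 3. Mesothelial markers stood at 1.03, 0.47 and 1.73 above the vector sham mean in the PRODH TAC libraries and at 3.33, 0.83 and 0.48 in vector TAC.

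In all, 449 genes rose and 382 fell with the PRODH virus after TAC, 723 of them by at least 1.5-fold. The total of 831 became 2719 without vector TAC replicate 1, 248 and 416 without replicates 2 and 3 of that group, and 339, 297 and 261 without PRODH TAC replicates 1, 2 and 3. DESeq2 on the recovered reads called 1493, a fit of only these 2 groups 383, and the fit without vector TAC replicate 1 and PRODH sham replicate 2 called 2830.

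In sham hearts, the PRODH virus left 0 genes past the threshold of limma. At an unadjusted p under 0.05 there were 871 genes. On the recovered reads edgeR called 0, limma voom 0 and DESeq2 6. Leaving out PRODH sham replicate 2 gave 1 gene and leaving out vector TAC replicate 1 gave 2. Nppb differed by 0.26 ± 0.18 and Nppa by -0.61 ± 0.41, both with limma adjusted p = 0.97. Lists of short transcripts stood higher in PRODH sham: the median was 0.29 over 76 oxidative phosphorylation genes and 0.35 over 44 ribosomal protein genes, with limma camera adjusted p = 2.2e-16 and 3e-09. Both had adjusted p = 0.67 with an estimated correlation, and 0 members passed, also adjusted over the list alone. Beside these lists, the change of a gene in this comparison fell with the length of its transcript (Spearman's rho = -0.43 across 9515 genes, which are not independent replicates). With a trend on length and GC content removed, in versions fitted on all genes and on genes with a mean above 100, the medians were 0.24 and 0.12 for oxidative phosphorylation and 0.3 and 0.19 for ribosomal proteins. The first version left rho = -0.202, so part of the trend remained, and the second left -0.001. Without vector sham replicate 2 the ribosomal median was 0.17. Immediate early genes had a median of 0.26 (limma camera adjusted p = 6.8e-06, and adjusted p = 0.67 with an estimated correlation). None of their 23 members passed over all genes and 3 did adjusted over the list alone. The median was 0.45 and 0.12 without vector sham replicates 1 and 3 and 0.05 without PRODH sham replicate 3. Mesothelial markers stood at 3.03 above the vector sham mean in PRODH sham replicate 2, against -0.06 and 0.16 in the other libraries of that group.

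Another 11 lists passed limma camera in PRODH sham hearts, each with 0 members called, also adjusted over the list alone, and adjusted p = 0.67 with an estimated correlation. Metabolic and muscle lists had medians of 0.18 for fatty acid oxidation (limma camera adjusted p = 1.4e-05), 0.16 for the tricarboxylic acid cycle (0.0043), 0.08 for branched-chain amino acid breakdown (0.041), 0.09 for antioxidant genes (0.019) and 0.14 for the sarcomere (0.025). The extracellular matrix list had -0.14 (0.0041), the interferon response -0.19 (0.0012) and endothelial markers -0.14 (0.007). Erythroid markers had 0.55 (0.011), Schwann and neuronal markers 0.46 (0.017) and mesothelial markers 1.01 (0.029). Single libraries moved all of these medians. Without vector sham replicate 1 they were 0.03 for branched-chain amino acid breakdown, 0.15 for antioxidant genes, -0.04 for the sarcomere, -0.27 for the matrix, -0.09 for the interferon response and 0.13 for Schwann and neuronal markers. Without vector sham replicate 2 the matrix had -0.08 and erythroid markers 0.35, and without replicate 3 the sarcomere had 0.26, the interferon response -0.31, endothelial markers -0.27 and erythroid markers 1.2. Without PRODH sham replicate 1 they were 0.11 for fatty acid oxidation, 0.08 for the tricarboxylic acid cycle, 0.01 for branched-chain amino acid breakdown, -0.08 for the matrix, -0.11 for the interferon response, -0.25 for endothelial, 1.26 for erythroid and 1.6 for mesothelial markers. Without PRODH sham replicate 2 they were 0.3 for fatty acid oxidation, 0.18 for branched-chain amino acid breakdown, 0.22 for the sarcomere, -0.24 for the matrix, -0.37 for the interferon response, 0.07 for erythroid, 0.2 for Schwann and neuronal and -0.1 for mesothelial markers. Without PRODH sham replicate 3 branched-chain amino acid breakdown had 0.05 and mesothelial markers 1.6.

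After TAC in PRODH mice, 4 genes rose and 1 fell. Ankrd1 rose by 1.61 ± 0.24, Nppb by 1.46 ± 0.18, the kelch-like gene Klhl34 by 1.36 ± 0.16 and Uck2, a kinase of the pyrimidine salvage pathway, by 1.08 ± 0.16. Ano10, an anoctamin membrane protein, fell by 1.03 ± 0.13. Limma adjusted p was 0.036 for Ankrd1 and Uck2 and 0.0066 for the others. Uck2 lies outside the naming rule and was chosen after its value was seen. Without PRODH sham replicates 1 and 3 and PRODH TAC replicates 1 and 3 in turn, no call was left, with Nppb at 1.47, 1.48, 1.49 and 1.39, Klhl34 at 1.32, 1.41, 1.35 and 1.34, Ano10 at -0.96, -1.01, -1.03 and -1.0, and Ankrd1 at 1.59, 1.69, 1.47 and 1.58. Uck2 stood at 1.03, 1.1, 0.88 and 1.11 there. Ankrd1 and Uck2 also lost their calls without PRODH sham replicate 2 (1.54 and 1.12) and vector TAC replicate 3 (1.61 and 1.08), and Uck2 without vector sham replicate 2 (1.08). Nppb went from 2626.7 ± 51.9 normalized reads to 7268.9 ± 656.8. Of 27 hypertrophy and fetal genes 2 rose (12 adjusted over the list alone), with limma camera adjusted p = 6.6e-12 and adjusted p = 0.09 with an estimated correlation. Of 77 extracellular matrix genes 0 passed (10 rose and 1 fell adjusted over the list alone), with a median of 0.46, limma camera adjusted p = 5.7e-11 and adjusted p = 0.7 with an estimated correlation. Cilp (2.0 ± 0.36), Acta1 (3.44 ± 0.64) and Ccn2 (1.49 ± 0.28) did not pass, with limma adjusted p = 0.079, 0.081 and 0.081. Of 34 interferon response genes 0 passed (6 rose adjusted over the list alone), with a median of 0.47 (0.3 without PRODH TAC replicate 2), limma camera adjusted p = 1e-11 and adjusted p = 0.7 with an estimated correlation. The oxidative phosphorylation list had a median of -0.47 (limma camera adjusted p = 1.3e-26, and adjusted p = 0.7 with an estimated correlation) with 0 of 76 members called. Ribosomal proteins, also short transcripts, had a median of -0.36. Medians were -0.32 for fatty acid oxidation, -0.27 for the tricarboxylic acid cycle and -0.24 for branched-chain amino acid breakdown. The change of a gene rose with transcript length in this comparison (rho = 0.476 across 9515 genes). Removal of the length and GC trend fitted on all genes left rho = 0.226 and an oxidative phosphorylation median of -0.41. Removal of that fitted on genes with a mean above 100 left rho = 0.017 and a median of -0.28.

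The count of 5 in PRODH mice differed between fits. A fit of the 2 PRODH groups alone called 1023 genes, 460 higher and 563 lower, and DESeq2 on the recovered reads called 124. Nppb changed by 1.46 in both limma fits, but its standard error was 0.08 in the fit of 2 groups and 0.18 over all groups. The median standard error was 0.19, against 0.3 with the spread shared by all 12 libraries. The fit of 2 groups called 652 genes in vector mice, all 652 by at least 1.5-fold and 505 by at least 2-fold. In PRODH mice 354 of the 1023 reached 1.5-fold and 121 reached 2-fold. The counts of 5 and 1645, or of 1023 and 652, therefore do not measure how far each response reached. The fit of 2 groups was not repeated with the length and GC trend removed. Of 5 genes called over all groups, the count became 0 without PRODH sham replicate 1 or 3 or PRODH TAC replicate 1 or 3, 3 without vector TAC replicate 3, 10 without vector sham replicate 1, 18 without vector sham replicate 3, 18 without PRODH TAC replicate 2 and 287 without vector TAC replicate 1. The fit without vector TAC replicate 1 and PRODH sham replicate 2 called 244.

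**Figure D4:**
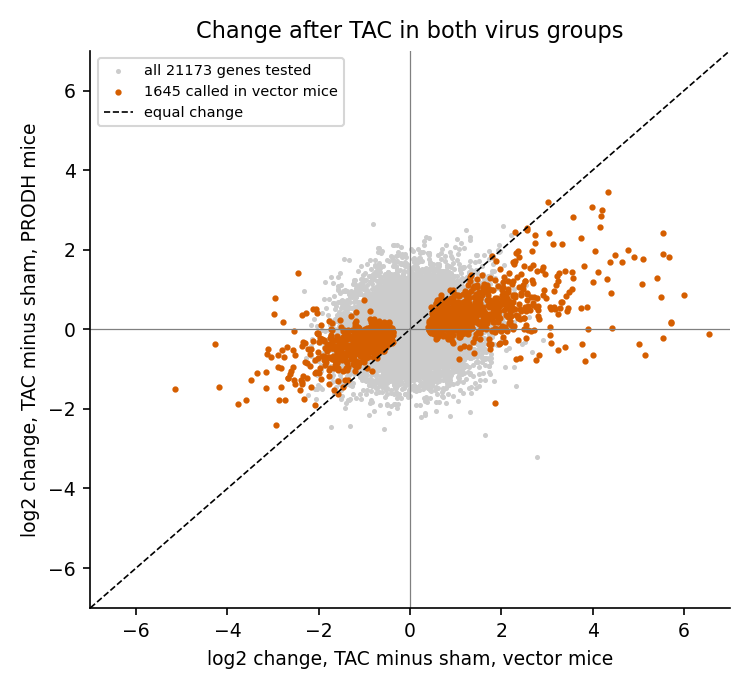
Log2 change after TAC in PRODH mice (vertical axis) against that in vector mice (horizontal axis), for 21173 genes (grey) and the 1645 called in vector mice (orange), with the line of equal change dashed. The called genes lie nearer to 0 on the vertical axis, with medians of 1.22 in vector mice and 0.34 in PRODH mice for the 787 that rose.

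The test of the difference between the responses to TAC of both virus groups called 22 genes, 10 with a higher and 12 with a lower change in PRODH mice. Fmod (-6.65 ± 1.17), Sprr1a, a stress-induced small protein (-5.74 ± 1.01), and Cthrc1 (-5.55 ± 0.91) had the most negative differences among named genes. Sprr1a had 1 read in vector sham. Klhl33 (1.94 ± 0.31), Lingo3 (1.83 ± 0.28) and Whrn (1.61 ± 0.28) had the most positive among named genes. Limma adjusted p lay between 0.026 and 0.046 for these 6 genes. Their calls were lost without most single libraries: Fmod (-7.37 to -5.49) without each except vector TAC replicate 1, and Sprr1a (-6.09 to -5.04) without each except vector TAC replicate 1 and PRODH TAC replicate 1. Cthrc1 (-5.95 to -5.02) and Whrn (1.4 to 1.74) kept theirs only without vector sham replicate 1 or vector TAC replicate 1, and Klhl33 (1.75 to 2.1) only without vector sham replicate 3 or vector TAC replicate 1. Lingo3 (1.68 to 1.9) kept its call only without vector sham replicate 1 or 3, vector TAC replicate 1 or PRODH TAC replicate 1. Of 77 extracellular matrix genes 4 were lower (39 adjusted over the list alone), with a median of -1.02, limma camera adjusted p = 1.8e-32 and adjusted p = 0.25 with an estimated correlation. Of 43 calcium handling and ion channel genes 1 was higher (10 adjusted over the list alone), with limma camera adjusted p = 9.9e-17 and adjusted p = 0.25 with an estimated correlation. Prodh had a difference of 1.26 ± 0.35 (limma adjusted p = 0.22). It passed at 1.45 without vector TAC replicate 1. The count of 22 became 0 without vector sham replicate 2, PRODH sham replicate 2, vector TAC replicate 2 or PRODH TAC replicate 3. It became 10 without vector sham replicate 3, 2 and 3 without PRODH sham replicates 1 and 3, 396 without vector TAC replicate 1, 5 without vector TAC replicate 3, and 7 and 1 without PRODH TAC replicates 1 and 2. It was 7 with edgeR, 6 with limma voom and 201 with DESeq2 on the recovered reads, and 246 without vector TAC replicate 1 and PRODH sham replicate 2.

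Both responses to TAC share no library and were set side by side across genes, which are not independent replicates. Pearson's r was 0.285 and Spearman's rho 0.267 over 21173 genes, 59.9% of which had the same sign, with a slope of 0.215, or 0.372 after correction for the error of the change in vector mice. Over all genes r became 0.243 without vector sham replicate 1, 0.221 and 0.24 without PRODH sham replicates 1 and 3, 0.325, 0.229 and 0.246 without vector TAC replicates 1, 2 and 3, and 0.237 without PRODH TAC replicate 1. Among 1645 genes called in vector or PRODH mice r was 0.743, and 88% had the same sign. Genes that rose in vector mice had a median of 1.22 there and 0.34 in PRODH mice, and genes that fell had medians of -0.83 and -0.29. Choosing genes by their change in vector mice by itself enlarges the value in vector mice.

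Of genes called after TAC in vector mice and genes called with PRODH in TAC mice, 695 were in both lists, and all 695 had opposite signs, 312 up after TAC and down with PRODH and 383 the reverse. Fmod, Thbs4, Postn and Nppa belong to the former and Aqp4, Retnla and Kcnj3 to the latter. They made up 42.2% of the first list and 83.6% of the second. Independent lists of these sizes would share 32.4 genes with opposite signs. Both comparisons contain the vector TAC libraries with opposite signs, which by itself makes the changes correlate negatively. Simulated groups without any effect gave a mean of 0.01 such genes, but only 0.12 called genes per comparison, so they set no chance level for lists of these sizes. The correlation of the changes was -0.719, against -0.501 in the simulation, and the covariance was -0.283, against -0.094. Taking the simulated covariance from the observed one leaves -0.189. Simulated groups without any effect have a mean of 0 there by design, so that mean is no further support. Pairs with vector TAC replicate 1 differed most among replicates (chi-square per degree of freedom 95.44 and 90.15), so sharing these libraries may account for more than was simulated. The 3 vector TAC libraries were not split between both comparisons, so a part that comes from sharing them is not excluded. The count became 2206, 221 and 367 without vector TAC replicates 1, 2 and 3, and 317, 266 and 246 without PRODH TAC replicates 1, 2 and 3. With DESeq2 on the recovered reads it was 1202.

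**Figure D5:**
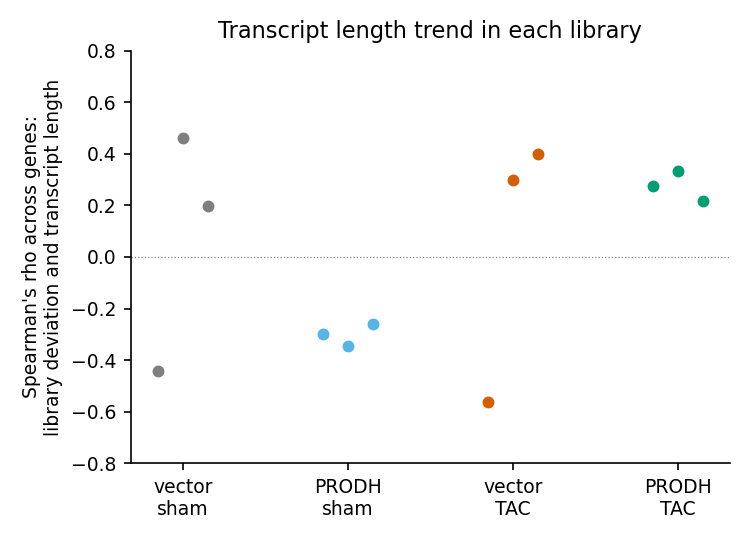
Spearman's rho across 9515 genes between transcript length and the deviation of each library from the mean of all 12 (vertical axis, linear), by group. Vector TAC replicate 1 reads -0.564 and replicates 2 and 3 read 0.298 and 0.401, while the PRODH sham libraries lie between -0.346 and -0.261 and the PRODH TAC libraries between 0.217 and 0.332.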

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

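Chosen only after the results were seen were the tests of scaling, of a weaker constriction, of dilution by other tissue, of a mislabelled heart and of lists of short transcripts, while the tests of other splits and of length and GC content in the first 2 patterns were written before their values were seen, except that the version fitted on genes with a mean above 100 came after the first version.

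In a test of the difference between the responses to TAC of PRODH and vector mice, 22 genes passed the threshold. Chance was not excluded for this count, as given below. Among genes that the text names, the differences were Fmod -6.65, Sprr1a -5.74, Cthrc1 -5.55, Chodl -5.38, Nupr1 -2.07, Mfap5 -1.97 and Mfap4 -1.96 on the negative side. On the positive side they were Klhl33 1.94, Lingo3 1.83, Whrn 1.61 and Hcn2 1.33. Each of these 11 genes lost its call without vector sham replicate 2, PRODH sham replicate 2 or 3, vector TAC replicate 2, or PRODH TAC replicate 2 or 3, taken singly. In vector sham Sprr1a had 1 read and Chodl had 0 reads, so their fitted differences depend on the added constant. The matrix-related lists had medians of -1.02 (extracellular matrix), -1.09 (TGF-beta and myofibroblast), -0.6 (fibroblast markers) and -1.68 (chondrocyte and valve markers), and hypertrophy and fetal genes -0.69, each with adjusted p = 0.25 with an estimated correlation. The metabolic lists had medians of 0.43 (fatty acid oxidation), 0.32 (tricarboxylic acid cycle) and 0.41 (branched-chain amino acid breakdown), with adjusted p = 0.41, 0.6 and 0.47 with an estimated correlation. Calcium handling and ion channels had 0.55 and the stress response -0.18, each with adjusted p = 0.25 with an estimated correlation. Smaller medians were -0.24 (endoplasmic reticulum stress) and -0.3 (cell cycle), with adjusted p = 0.7 and 0.84 with an estimated correlation. Macrophage markers had -0.44, mesothelial markers -1.51 and ribosomal proteins -0.45, with adjusted p = 0.7, 0.53 and 0.82 with an estimated correlation. Without vector TAC replicate 1 and PRODH sham replicate 2 together these 3 were -0.01, 0.94 and 0.06 and did not pass. Without vector TAC replicate 1 alone they were -0.2, -0.22 and 0, and without PRODH sham replicate 2 alone macrophage markers were -0.26 and mesothelial markers -0.3, none of which passed. The medians also moved for hypertrophy genes (-0.43 without PRODH TAC replicate 2), the tricarboxylic acid cycle (0.21 without vector TAC replicate 2) and chondrocyte and valve markers (-2.54 without vector TAC replicate 1). They moved for ribosomal proteins without vector sham replicate 2 (-0.27) and vector TAC replicate 2 (-0.68), for the stress response without vector TAC replicate 1 (-0.11) and PRODH TAC replicate 1 (-0.28), for endoplasmic reticulum stress without vector TAC replicate 1 (-0.39) and for cell cycle genes without PRODH sham replicate 1 (-0.51). Calls were also lost by cell cycle genes without vector sham replicate 3 (0.02), PRODH sham replicate 2 (-0.02), vector TAC replicates 1 (-0.27) and 2 (-0.19) and PRODH TAC replicates 1 (-0.33) and 3 (-0.31). Endoplasmic reticulum stress lost its call without vector sham replicate 3 (-0.12), PRODH sham replicate 1 (-0.22) and vector TAC replicates 2 (-0.2) and 3 (-0.14). The stress response lost its call without vector sham replicate 3 (-0.23), PRODH sham replicates 1 (-0.26) and 3 (-0.2), vector TAC replicates 2 (-0.2) and 3 (-0.19) and PRODH TAC replicate 2 (-0.2).

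The counts of genes were set beside other splits of the same libraries. For TAC in vector mice 1 of 10 splits, the real one, called as many genes, and the highest other split called 856. It joined vector sham replicates 1 and 3 with vector TAC replicate 1, and called 0 in both versions with the length and GC trend removed, where the real split called 2187 and 2286. For PRODH in TAC mice and for TAC in PRODH mice 1 of 10 called as many, and the highest other split called 0. For PRODH in sham mice 10 of 10 called as many as the real split, which called 0. With 10 splits the smallest possible share is 10%, so chance could not be tested at 0.05. For the difference between the TAC responses 9 of 100 drawn assignments, the real one included, called at least 22 genes, the highest 288. That highest assignment exchanged the sham groups and therefore carried the effect of PRODH in TAC mice. Any assignment that kept the split of the TAC libraries, or its mirror, also carried this effect. The share is therefore no clean chance level, so this test could not decide about chance, which was not excluded for this count.

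The first pattern weighed was the smaller response to TAC in PRODH hearts, in which the extracellular matrix list differed by -1.02. Under 4 other scalings its highest median was -0.97. These scalings differed little, since the difference had a median over all genes between -0.015 and 0.037. The list could hardly have moved, so the values show only that the choice among these scalings did not produce it. With the length and GC trend removed the list median was -1.06 in both versions, which argues against that trend as the cause. A weaker constriction in PRODH mice could shrink all gene groups alike; among the 11 lists called in both virus groups with the same direction, the highest kept fraction of a list mean was 1.09 (oxidative phosphorylation) on the deposited values, the value first written for this test, and that list kept 0.64 and 1.72 without vector TAC replicates 1 and 2. Since that list holds short transcripts and changes after TAC in PRODH mice rose with length, values with the trend removed were added after the first was seen: the list kept 0.89 and 0.71 in the versions, and the highest of these 11 lists was 0.89 and then 0.9 (interferon response). The version fitted on all genes left part of that length trend (rho = 0.226, against 0.017 in the other). The lowest of the 11 deposited fractions was 0.19, but responses to load need not scale evenly and no pressure was measured in the table, so a weaker constriction stays open, as does an effect of PRODH itself, which no test here separates from it.

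The second pattern was vector TAC replicate 1, whose gap to the mean of replicates 2 and 3 was -1.35 in the extracellular matrix list and 2.68 in mesothelial markers. Dilution by other tissue as the cause of the matrix gap would lower ventricular myocyte markers alike. Yet their gap was 0.16 ± 0.15, above the matrix gap by 1.51, more than their mean change of -0.34 after TAC could hide. Here ± is a standard error over the marker genes, which are not independent replicates, and does not measure the spread between animals. The gap compares 1 library with 2. A small share of other tissue stays open, since adipocyte (1.55), erythroid (2.44), neutrophil (1.37) and T and NK cell markers (1.26) were all higher in this library. With the trend fitted on genes with a mean above 100 removed, these gaps were 1.12, 1.85, 0.83 and 0.81. Some members had few reads over the vector TAC group, such as Camp (3), Ngp (2), Adipoq (6) and Cd3e (9). Ribosomal proteins, a list of short transcripts, also had a gap of 1.37, and 0.79 with that trend removed. With the length and GC trend removed the matrix gap was -1.12 in both versions, which argues against that trend as its whole cause, and hypertrophy genes stood 0.86 above the highest sham library, against a range of 0.54 among the sham libraries, which argues against a mislabelled sham heart. A milder response of this animal was not tested and also stays open.

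The third pattern was the higher level of lists of short transcripts in PRODH sham hearts. With the trend fitted on all genes the median of the oxidative phosphorylation list went from 0.29 to 0.24 and that of ribosomal proteins from 0.35 to 0.3. This version took out only part of the trend. The correlation between change and transcript length across 9515 genes went from -0.43 to -0.202. On the deposited values the ribosomal median was 0.17 without vector sham replicate 2. With the trend fitted on genes with a mean above 100 both medians were 0.12 and 0.19, the former under and the latter just over 0.5 of the deposited median. This version left a correlation of -0.001 with length, on the same genes that it was fitted on. Only the second version took the length trend out, and there the lists fell on different sides of 0.5 of their deposited medians. A length and GC trend and a biological effect of the virus could therefore not be told apart.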

How the results depend on the processing

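The tests chosen only after results were seen were edgeR with TMM, TMM scaling, thinning, the fit without the 2 libraries richest in mesothelial reads (vector TAC replicate 1 and PRODH sham replicate 2), the mesothelial covariate and the removal of length and GC trends. Of the comparisons of single genes and lists with other settings, 5274 were the same, 483 weaker, 32 stronger and 5 reversed. For counts and Prodh, 352 were the same, 93 moved and 11 were stronger. No called gene changed sign under any setting. Where a value below differs, the cause was not tested.

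With only the 2 groups compared, TAC in vector mice called 652 genes, PRODH in TAC mice 383 and TAC in PRODH mice 1023. Of these, 652, 380 and 354 changed by at least 1.5-fold. Median standard errors there were 0.28, 0.25 and 0.19, against 0.3 in the main fit. DESeq2 called 1493 for PRODH in TAC mice, 6 in sham mice, 124 for TAC in PRODH mice and 201 for the difference between TAC responses. Without the 2 mesothelial-rich libraries the 5 counts were 3513, 2830, 2, 244 and 246. The covariate gave 1 for PRODH in sham mice and 14 for TAC in PRODH mice. Trend removal fitted on all genes gave 26 for TAC in PRODH mice and 65 for the difference. Fitted on genes with a mean above 100 it gave 1388 for PRODH in TAC mice, 35 for TAC in PRODH mice and 39 for the difference. For TAC in PRODH mice library size scaling gave 12, upper quartile 3 and edgeR with no filter 32. For the difference, pseudocount 0.1, a stricter filter, edgeR with TMM and edgeR with DESeq2 size factors each gave 7, edgeR with no filter 47 and limma voom 6.

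Prodh after TAC in vector mice passed at -0.85 with quantile normalization, -0.81 with DESeq2, -1 without the 2 mesothelial-rich libraries and -0.88 with the trend fitted on all genes removed. In sham mice it passed at 1.33 with DESeq2 and 1.61 without those libraries, and its difference between TAC responses passed at 1.11 without them. Lists called with an estimated correlation were 0 in all 5 comparisons. In sham mice quantile normalization called 9 lists, the fit without those libraries 22 and fry 0. Fry called 1 for TAC in PRODH mice and 0 for the difference. The correlation of TAC responses was 0.505 under a stricter filter, 0.743 among called genes and 0.336 without those libraries. Opposite changes numbered 1202 with DESeq2 and 2305 without those libraries.

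In the difference between TAC responses the direction given by camera turned for some lists, none of which passed there, and their medians were near 0 in all but the mesothelial list. They were cell cycle 0.02 without vector sham replicate 3 and ribosomal proteins 0 without vector TAC replicate 1. Without the 2 mesothelial-rich libraries they were macrophage markers -0.01, mesothelial markers 0.94 and ribosomal proteins 0.06.

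With each library left out in turn, the counts in the order of the comparisons ran from 817 to 3420, 248 to 2719, 0 to 2, 0 to 287 and 0 to 396. Prodh ran from -1 to -0.7, 2.39 to 2.71, 1.05 to 1.61, 0.1 to 0.66 and 0.92 to 1.47. Lists called ran from 18 to 24, 15 to 20, 9 to 19, 13 to 20 and 13 to 18. In the difference between TAC responses, cell cycle ran from -0.51 to 0.02 and ribosomal proteins from -0.68 to 0. The correlation ran from 0.221 to 0.325 and opposite changes from 221 to 2206.

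With the replicate number as a block the counts were 1737, 914, 0, 5 and 35. The 18 pairs of libraries with the same number correlated at -0.049 to 0.14 (median 0.004), against -0.206 to 0.142 in other pairs, and 5 of 12 libraries correlated best with their own number. These values gave no clear sign of pairs, but they cannot exclude a shared litter, batch or day. The fit of 2 groups has no value for the difference between responses, and the comparison of deposited counts with normalized values was not run, since the table holds only the latter. Depth limits genes with few reads: vector TAC replicates 2 and 3 (13.9 and 15.2 M reads) had a read in 20482 and 20410 genes, and the other libraries (10.1 to 12.3 M) in 18909 to 19726.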

Other observations

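The tests behind these values were fixed beforehand, but the selections of genes, except Klhl34, were chosen only after the values were seen, and no explanation was tested.

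Some genes had similar values after TAC with either virus. Klhl34, a kelch-like gene, rose by 1.34 ± 0.16 in vector mice and 1.36 ± 0.16 in PRODH mice, and passed in both (limma adjusted p = 0.00013 and 0.0066, n = 3 per group). The call in PRODH mice was lost without PRODH sham replicate 1 (1.32) or 3 (1.41) or PRODH TAC replicate 1 (1.35) or 3 (1.34). Ankrd23, a titin-binding stretch sensor, had 1.46 ± 0.2 and 1.26 ± 0.2, Ccn1, a matricellular protein, 1.3 ± 0.22 and 1.22 ± 0.22, and Mthfd2, a mitochondrial folate enzyme, 1.27 ± 0.24 and 1.11 ± 0.24. Nmb (neuromedin B) had -1.58 ± 0.39 and -1.64 ± 0.39, and lost its call in vector mice without vector sham replicate 1 (-1.57) or 3 (-1.37) or vector TAC replicate 2 (-1.32) or 3 (-1.26). In PRODH mice these 4 did not pass (limma adjusted p = 0.054, 0.079, 0.14 and 0.2). In all, 68 of 1645 genes called in vector mice (4.1%) kept at least 0.8 of their change in PRODH mice, and 2 of them were called between PRODH TAC and vector TAC. Choosing genes by their call in vector mice enlarges the change there and so lowers this share. No chance level was set beside it.

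Other genes differed between PRODH TAC and vector TAC with an unadjusted p of at least 0.05 for TAC in vector mice. They numbered 37 of 831, 20 higher and 17 lower. Klhdc8a rose by 0.85 ± 0.16 and Cited4, a transcriptional coactivator, by 0.68 ± 0.14, while Fkbp5, a glucocorticoid-induced chaperone, had -0.81 ± 0.18. These calls were lost by Klhdc8a without vector TAC replicate 2 (0.7) or PRODH TAC replicate 3 (0.78), and by Cited4 without vector TAC replicate 3 (0.66) or PRODH TAC replicate 2 (0.64) or 3 (0.65). Fkbp5 lost its call without vector TAC replicate 3 (-0.82) or PRODH TAC replicate 1 (-0.78) or 3 (-0.72). After TAC in vector mice Klhdc8a had -0.28 ± 0.16, Cited4 -0.3 ± 0.14 and Fkbp5 0.24 ± 0.18, each opposite in sign to its difference with PRODH. Both comparisons contain the vector TAC libraries with opposite signs, which by itself favors opposite signs in genes chosen by their difference with PRODH. In sham hearts the difference with PRODH was 0.13 ± 0.16 for Klhdc8a, 0.18 ± 0.14 for Cited4 and -0.54 ± 0.18 for Fkbp5 (limma adjusted p = 0.97 for each). The difference between TAC responses was 0.72 ± 0.23, 0.51 ± 0.2 and -0.28 ± 0.25 (limma adjusted p = 0.31, 0.5 and 0.82). No reversal of a change after TAC was therefore shown for these genes. An unadjusted p over the cutoff does not show that TAC left a gene unchanged.

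In the fit of the PRODH groups alone 1023 genes were called after TAC, 354 of them by at least 1.5-fold. Postn had 1.43 ± 0.08 there, Ccn2 1.49 ± 0.07 and Cilp 2 ± 0.14. Of these genes 89.3% had the same sign in vector mice, and 376 were also called there, 375 with the same sign.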
